A study of Mus musculus with 15 samples.

How the data were processed

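ATAC-seq libraries were made from T cells of lymph node and lung and from lung ILC2 of WT and KO Balb/c mice. Per the labels' protocols, sorted cells were lysed in mild detergent, their nuclei incubated with Nextera transposase, and the amplified libraries sequenced as short paired-end reads. Reads were aligned with BWA and peaks called with MACS2 on mm9, per the submitters' processing notes, which give no versions here. Whether reads were shifted for the transposase offset, and how duplicates were removed, is not given in the sources used here. Each of the 15 samples has a peak list of its own, so peaks were called per sample and not on pooled samples. Groups and replicate numbers were read from the labels. One source label of the KO ILC2 sample reads ILC4 where its other labels read ILC2, and it was used as ILC2. The labels do not say whether replicates came from separate mice, so p-values measure the spread between these samples, which can be partly technical.

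The deposited lists have no header, and their columns follow the narrowPeak layout. For each peak they hold the authors' fold enrichment at the summit, a linear ratio of signal to local background. They also hold the authors' −log10 p-value and −log10 q-value, and the distance of the summit from the start. These are values of the peak itself and were used only to describe, rank or filter peaks within a list. In all 62448 peaks the deposited fold and −log10 p gave back a whole-number summit height and a local background, through fold = (height + 1)/(background + 1) and the Poisson tail of the height. The tolerance was 0.002 in −log10 p, and a whole height was found for 100% of peaks in every library. The number of reads sequenced is not given in the sources used here, and the median summit height, 6 to 13 reads, stood in for depth, which it does not separate from enrichment quality.

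Intervals were converted to 1-based coordinates. The region and ILC2 comparisons used peaks on chromosomes 1 to 19, X and Y, while peak number and similarity used the full lists. Peaks of the 13 T cell libraries that shared 1 bp or more were merged into regions. A region was tested where at least 2 of the libraries compared called it. Since libraries differ in list length, each received a weight by conditional maximum likelihood of a Rasch model. Given how many libraries called a region, the exact 2-sided p of the calls in one group was computed under these weights. Benjamini-Hochberg adjustment was applied over all regions of a comparison at 0.05. Peak number was compared on the log2 scale, and tissue labels were permuted within genotype. Similarity was the share of the N strongest peaks that overlapped, with N the shortest list compared (188), and its 1-sided exact permutation test asked whether pairs within a group shared more than pairs between groups. Shares of ILC2 peaks have exact Clopper-Pearson intervals at 95%. Named regions are those fixed by rule before the data were examined: for each comparison and direction, the 10 with the smallest exact p, ties ordered by the difference in the share of libraries calling, then by the number of libraries calling, then by position. Ties at the last place were common, up to 52 regions, so the named ones are often only the first by position. Some regions were chosen after their values were seen. These are the 2 found in both ILC2 libraries but in no T cell library, the strongest ILC2 peaks without a T cell region, and the regions called in all T cell libraries.

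Tests were run first on simulated data. In 1644 simulated peaks every height was recovered (100%). For the comparison of tissues (10254 regions), simulated calls without any difference gave 0 regions after adjustment and 1.60% at an unadjusted p under 0.05. With 200 simulated regions given 100-fold odds in lung, 0 passed adjustment and 47.0% reached an unadjusted p under 0.05. With 1000-fold odds at regions called in as many libraries as lung has, 49.5% of 200 passed adjustment. For KO against WT in lymph node (7313 regions), 0 of 200 passed adjustment at either size, and 17.0% and 38.5% reached an unadjusted p under 0.05. In these simulations adjusted calls arose only in the comparison of tissues, at near-complete separation.

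No 2 libraries were duplicates: at most 15 intervals were identical between a pair of lists, and at most 1.60% of the shorter list. Other settings, fixed before the data were examined, were a stricter threshold (−log10 q of at least 5), leaving out libraries of under 1000 peaks, leaving out each replicate in turn, replicate number as a block, an unweighted test, merging over gaps of up to 500 bp, 200 bp windows around summits, regions called in at least 3 libraries, each genotype alone, 50% reciprocal overlap, all peaks over the shorter list, and ranking by fold. Leaving out peaks whose background exceeded 10 times the library's lowest, comparing the top 1000 peaks of libraries with at least 1000, and the stricter threshold for ILC2 shares were chosen after seeing the data. The intended share of peaks at promoters, counts of genes called and gene lists need an mm9 gene annotation, which was not used here, since the gene table at hand describes GRCm38. Regions are therefore given by position without gene names. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.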

Results

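Chromatin accessibility was profiled by ATAC-seq, in which a transposase cuts and tags open chromatin, in T cells and group 2 innate lymphoid cells (ILC2, tissue-resident lymphocytes that secrete type 2 cytokines) from Balb/c mice. The 15 libraries fell into 6 groups. Lymph node T cells came from wild-type mice (WT, n = 5) and from mice lacking cytokine genes that the labels do not name (KO, n = 3). Lung T cells came from WT (n = 2) and KO mice (n = 3), and lung ILC2 were represented by 1 WT and 1 KO library. Each library had its own list of accessible regions (peaks), in coordinates of the mouse build mm9. Per the labels, lymph node CD4 T cells were cultured under conditions that favour Th2 differentiation, but that protocol is attached to every sample, lung and ILC2 included.

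The lists ranged from 188 to 10708 peaks and covered 0.0907 to 4.52 Mb of the genome. Lymph node WT T cells had 3718 ± 2368 peaks (mean ± SD, n = 5) and lymph node KO T cells 5137 ± 4615 (n = 3). Lung WT T cells had 5560.5 ± 7280 peaks (n = 2) and lung KO T cells 5189 ± 2631 (n = 3). The WT ILC2 library had 1382 peaks and the KO ILC2 library 378. Among the T cell libraries, 3 had fewer than 1000 peaks: lymph node KO replicate 3 with 188, lung WT replicate 3 with 413 and lymph node WT replicate 4 with 520. The median height of a peak at its summit was 6 to 13 reads, so most peaks rested on few reads. Longer lists came from libraries with higher summits: over the 15 libraries, log2 peak number correlated with the median summit height (Pearson r = 0.797, permutation p = 5.4e-04; Spearman rho = 0.853, permutation p = 1.8e-04; adjusted over 6 relations, 0.0027 and 0.00054). Without the 2 libraries farthest from the median height r was 0.742, and among the 8 lymph node T cell libraries alone r was 0.795.

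**Figure D1:**
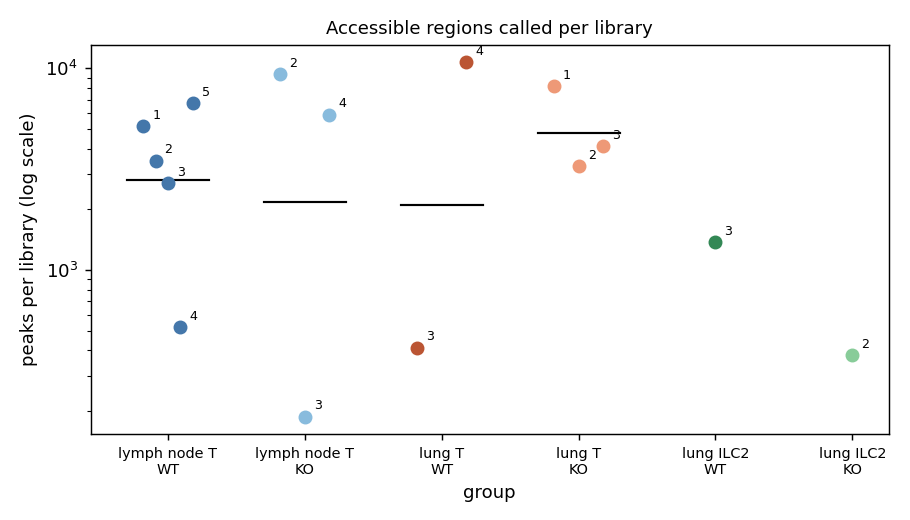
Peaks per library on a log axis, by group; each point is 1 library with its replicate number, and black lines mark geometric means. Within lymph node KO T cells the lists ran from 188 to 9322 peaks and within lung WT T cells from 413 to 10708, wider than any difference between group means.

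The peaks of the 13 T cell libraries merged into 19662 separate regions on chromosomes 1 to 19, X and Y. Of these, 9408 (47.8%) were called in 1 library, 10254 in 2 or more, 747 in 10 or more and 35 in all 13. The shortest list, with 177 peaks on these chromosomes, limits how many regions all 13 can share. Of these 35 regions, 32 were also called in both ILC2 libraries. The tallest was on chromosome 2 at 98506407 to 98507468, with a median summit of 352 reads and a median fold enrichment of 5.32 over the 15 libraries. Another, on chromosome 9 at 35112801 to 35113176, had a median fold of 21.3 and a median summit of 234 reads. A local background over 10 times the lowest of its library was found in 1 or more libraries at 27 of the 35 regions. Common regions of low background included chromosome 1 at 131293628 to 131294634 (median fold 13.1) and chromosome 2 at 74236897 to 74237656 (median fold 10.3).

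The first comparison asked whether T cells of the lung and of the lymph node differ in open chromatin. At an unadjusted exact p under 0.05, 227 of 10254 regions were called more often in lung T cells and 98 more often in lymph node T cells, where list lengths alone would give 92.8 and 81.9. No single region passed Benjamini-Hochberg adjustment at 0.05 in the exact conditional test, and 0 passed in the unweighted Fisher's exact test, which left 212 lung and 0 lymph node regions at an unadjusted p under 0.05. A pair of regions separated the tissues completely, with calls in 5 of 5 lung and 0 of 8 lymph node T cell libraries: chromosome 13 at 24578998 to 24579675 and chromosome 18 at 33129516 to 33130360 (each exact p = 1.66e-05, adjusted p = 0.0852). Their summits reached 5 to 19 reads (fold 5.10 to 7.78) and 7 to 28 reads (fold 5.39 to 9.26) in the lung libraries, and neither ILC2 library called them. Their low p, like that of other regions called in all 5 lung libraries, rests on lung WT replicate 3. That list of 413 peaks has a weight of 0.0260, against 18.3 for lung WT replicate 4. Without it the smallest possible exact p towards lung is 0.00264, and Fisher's exact test on all 13 libraries can give no less than 0.000777.

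Further lung-preferring regions were called in all 5 lung libraries and in few lymph node libraries. The region on chromosome 7 at 91300048 to 91300806 was called in 1 of 8 lymph node libraries (exact p = 0.00018, adjusted p = 0.615). Regions on chromosome 3 at 96042721 to 96043749, chromosome 6 at 39329310 to 39330069 and chromosome 8 at 59906281 to 59907032 were each called in 2 of 8 (exact p = 0.00109, adjusted p = 0.913). A further 23 regions tied, with calls in 4 of 5 lung and 0 of 8 lymph node libraries (exact p = 0.00276, adjusted p = 0.913). The first 4 by position, called in all lung libraries but WT replicate 3, complete the 10 named. They lie on chromosome 1 at 61102871 to 61103546 and at 182333648 to 182334137, on chromosome 4 at 40728381 to 40729199 and on chromosome 5 at 24728575 to 24729002, with folds of 4.20 to 11.7.

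Lymph node T cells had no region called in every one of their libraries and absent from lung. Lymph node KO replicate 3 and WT replicate 4, lists of 188 and 520 peaks, left little room for one, so this says little about the tissues. At the lowest p towards lymph node, 11 regions tied, each called in 5 of 8 lymph node and 0 of 5 lung libraries (exact p = 0.00356, adjusted p = 0.913). The first 10 by position are the named ones. Among them, chromosome 1 at 97164505 to 97164987 reached a fold of 11 and 25 reads, chromosome 2 at 145022624 to 145023306 a fold of 8.90 and chromosome 15 at 85063414 to 85064030 a fold of 8.89. Both KO libraries of over 1000 peaks called each of these 10 regions, and neither ILC2 library called any.

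**Figure D2:**
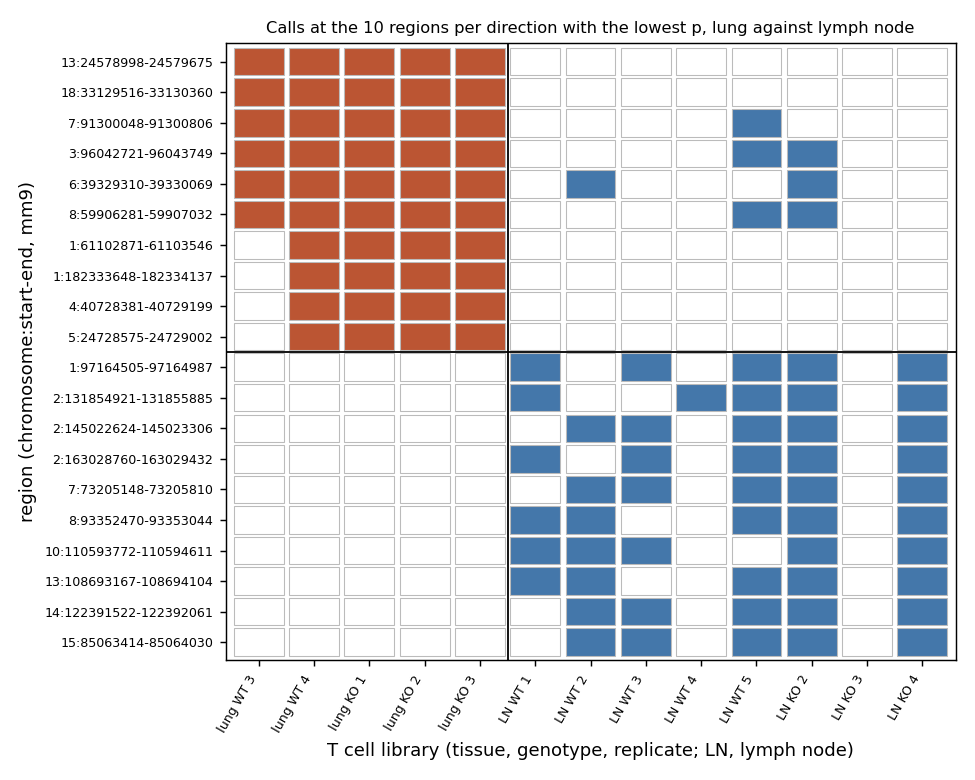
Calls (filled) at the 10 regions per direction with the lowest exact p in the comparison of lung with lymph node T cells, ties cut by position; rows are regions in mm9 coordinates and columns the 13 T cell libraries. The regions were selected for their p, so the separation shown is that of the selection; 2 regions were called in 5 of 5 lung and 0 of 8 lymph node libraries.

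With WT libraries alone, 76 lung and 9 lymph node regions had an unadjusted exact p under 0.05, where list lengths alone would give 49.2 and 24.1. With KO libraries alone they were 54 and 13, where list lengths alone would give 22.8 and 19.3. When single long lymph node lists were left out, the counts were 59 lung and 139 lymph node regions without KO replicate 2, 121 and 128 without KO replicate 4, and 117 and 121 without WT replicate 5. List lengths alone would give 28.1 and 100, 63.4 and 78.5, and 68.9 and 72.0 there. Without lung KO replicates 1, 2 and 3 the counts were 105 and 29, 150 and 86, and 108 and 76, where list lengths alone would give 50.1 and 28.2, 58.6 and 64.9, and 47.1 and 70.8. The lymph node count was 44 without lung WT replicate 4, and 49 and 52 without lymph node WT replicates 1 and 2 (42.8, 30.8 and 42.7 from list lengths alone). Without the 3 libraries of under 1000 peaks the counts were 203 and 91 (76.8 and 73.9 from list lengths alone). With the stricter threshold of −log10 q of at least 5 they were 97 and 77, and what list lengths alone would give there was not computed. Towards lung the smallest possible exact p was 0.00237 with WT alone, 0.0118 with KO alone and 0.00264 without libraries of under 1000 peaks. Towards lymph node it was 0.00202, 0.000316 and 0.000391 in that order. Regions could pass adjustment there only if many shared such a p, so 0 past adjustment in these settings says little.

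The number of accessible regions did not differ detectably between the tissues. Lung T cell lists were 1.29 times as long as lymph node lists in geometric mean (log2 difference 0.36, genotypes averaged; 2-sided exact permutation p = 0.729 over 420 arrangements, smallest possible p 0.00476). Of the 188 strongest peaks per library, lung pairs shared 38.9%, lymph node pairs 39.2% and mixed pairs 38.6% on average. Between 13.3% and 19.7% of these peaks in each T cell library lay at the 35 regions called in all 13. Pairs of any kind can share such regions, and how far this brings the averages together was not tested. The mean within tissues exceeded that between them by 0.552 percentage points (1-sided exact permutation p = 0.336). It was 2.26 points with the 1000 strongest peaks of libraries with at least 1000, a setting chosen after seeing the data (1-sided exact permutation p = 0.06), and 2.44 points with all peaks over the shorter list (1-sided exact permutation p = 0.155). The excess reversed in sign under several settings. Library numbers in the labels run from lymph node to lung. The labels do not say whether they follow processing order, and if they do, tissue and processing order cannot be told apart.

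The second comparison asked how loss of the cytokine genes bears on lymph node T cells. No region was shown to differ between KO and WT lymph node T cells. Of 7313 regions, 14 were called more often in KO and 59 more often in WT at an unadjusted exact p under 0.05, where list lengths alone would give 21.8 and 47.0. None passed adjustment in the exact conditional test (lowest adjusted p = 1) or in Fisher's exact test, which left 2 KO and 0 WT regions at an unadjusted p under 0.05. The regions on chromosome 8 at 11008334 to 11009649 and chromosome 10 at 75226739 to 75227243 were called in 3 of 3 KO and 0 of 5 WT libraries (each exact p = 0.000343, adjusted p = 1), with folds of 4.88 to 8.02 and 5.21 to 8.46. Those on chromosome 5 at 109985928 to 109987938 and chromosome 17 at 57150493 to 57151411 were called in 3 of 3 KO and 1 of 5 WT libraries (exact p = 0.00167, adjusted p = 1). These low p-values rest on the calls of KO replicate 3, a list of 188 peaks with a weight of 0.00777.

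Among the lymph node libraries, only those of WT T cells called chromosome 3 at 130512727 to 130513395, chromosome 16 at 17451768 to 17452365 and chromosome 17 at 71834968 to 71836057, each in 4 of 5 WT and 0 of 3 KO libraries (exact p = 0.00533, adjusted p = 1). Chromosome 1 at 182743322 to 182744268, chromosome 6 at 92041369 to 92042406, chromosome 13 at 24892552 to 24893277 and chromosome 18 at 32070101 to 32071042 were called in 5 of 5 WT and 1 of 3 KO libraries (exact p = 0.00918, adjusted p = 1). In 1 of the 2 ILC2 libraries the regions on chromosomes 6 and 18 were called as well.

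Without KO replicate 3, the library of 188 peaks, no region could reach an unadjusted p under 0.05 towards KO (smallest possible exact p 0.330), so the 0 KO regions there say nothing, and 59 were more frequent in WT (46.6 from list lengths alone). The WT count was 4 without KO replicate 2, 9 without KO replicate 4, 23 and 29 without WT replicates 2 and 3, and 126 and 178 without WT replicates 5 and 1. List lengths alone would give 5.90, 24.3, 23.7, 34.1, 81.8 and 126 in that order.

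Peak number showed no detectable difference between the genotypes in lymph node T cells. The KO lists were 0.78 times as long as the WT lists in geometric mean (log2 difference −0.36, 2-sided exact permutation p = 0.893 over 56 arrangements, smallest possible p 0.0357). Without the libraries of under 1000 peaks the sign turned (0.80, exact permutation p = 0.267). The arithmetic means went the other way, 5137 peaks in KO against 3718 in WT. Of the 188 strongest peaks, KO pairs shared 32.3%, WT pairs 42.9% and mixed pairs 38.1% on average; the mean within genotypes was 2.34 percentage points above that between them (1-sided exact permutation p = 0.196, smallest possible p 0.0179). That difference turned to −3.59 points without KO replicate 3 and to −2.47 without the libraries of under 1000 peaks.

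In lung T cells the same genotype comparison had 3 KO and 2 WT libraries. Calls in 3 of 3 KO and 0 of 2 WT libraries were found at 43 of 6947 regions (exact p = 0.0353), and these made up all regions more frequent in KO at an unadjusted p under 0.05. Another 92 regions were more frequent in WT at that level, of which 9 were called in 2 of 2 WT and 0 of 3 KO libraries (exact p = 0.00161). List lengths alone would give 49.5 and 91.9. The counts were 79 KO and 13 WT regions at the stricter threshold and 54 and 36 with summit windows. What list lengths alone would give in these settings was not computed, so whether the balance turned beyond it is not known. No region passed adjustment in the exact conditional test, and Fisher's exact test cannot give a p under 0.1 with 3 and 2 libraries.

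Lung regions called in 3 of 3 KO and 0 of 2 WT libraries included chromosome 1 at 59969623 to 59970368 (fold 5.70 to 9.44) and chromosome 2 at 3341154 to 3341839 (fold 4.19 to 8.36). Those called in 2 of 2 WT and 0 of 3 KO libraries included chromosome 1 at 197074046 to 197074646 (fold 4.35 to 7.46) and chromosome X at 137430130 to 137430601 (fold 4.99 to 9.24). Both ILC2 libraries called the region on chromosome X. Leaving out either WT library leaves 1, and then the test cannot reach an unadjusted p under 0.05 in one direction: towards WT without replicate 3, the library of 413 peaks, and towards KO without replicate 4 (smallest possible exact p 1 in each). Without KO replicates 2, 3 and 1 the KO count was 178, 158 and 70, and list lengths alone would give 177, 157 and 70.1.

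KO lists in the lung were 2.28 times as long as WT lists in geometric mean (log2 difference 1.19, 2-sided exact permutation p = 0.8 over 10 arrangements, where the smallest possible p is 0.2). Without WT replicate 3 the log2 difference was −1.16. The arithmetic means went the other way, 5189 peaks in KO against 5560.5 in WT. The genotype difference in peak number, set between tissues, was 1.55 higher in lung than in lymph node on the log2 scale (2-sided exact permutation p = 0.518 over 560 arrangements). It turned to −1.96 without the libraries of under 1000 peaks (2-sided exact permutation p = 0.0667) and to −0.80 without lung WT replicate 3.

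The last comparison set lung ILC2 beside T cells, with 1 library per genotype and therefore no test between groups. In each ILC2 library most called peaks overlapped a region of 1 or more lung T cell libraries. Most also overlapped a region of 1 or more lymph node T cell libraries. In the WT ILC2 library 56.1% of 1347 peaks (95% exact binomial interval 53.4 to 58.8) overlapped a lung T cell region and 55.5% (52.8 to 58.2) a lymph node T cell region. In the KO ILC2 library these shares were 73.1% of 350 peaks (68.2 to 77.7) and 72.3% (67.3 to 76.9). Overlap restricted to lung T cells was found for 62 WT and 17 KO ILC2 peaks, and overlap restricted to lymph node T cells for 54 and 14. No test of a preference was run on these counts, and the lung regions come from 5 libraries and the lymph node regions from 8. The intervals cover counting error only. The lists of 1347 and 350 peaks are short and need not stand for all accessible regions of ILC2. The higher shares, in KO, came from the shorter list, and whether list length accounts for them was not tested.

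ILC2 peaks with no T cell counterpart made up 39.9% (37.2 to 42.5) of the WT and 22.9% (18.6 to 27.6) of the KO list. For the T cell libraries, the share of peaks found in no other T cell library was 7.0% to 37.9%. Among peaks with −log10 q of at least 5, the share without a T cell region was 18.3% (42 of 229, 13.5 to 24.0) in WT ILC2 and 4.65% (4 of 86, 1.28 to 11.5) in KO ILC2, against 0 to 13.5% in the T cell libraries. The strongest WT ILC2 peaks outside T cell regions lay on chromosome 12 at 94815432 to 94815672 (fold 13, 22 reads), chromosome 16 at 14218647 to 14218905 (fold 9.65) and chromosome 5 at 28425751 to 28425960 (fold 9.45). In KO ILC2 they lay on chromosome 16 at 93992877 to 93993256 and chromosome 2 at 43751616 to 43751911 (each fold 8.17, 12 reads). The WT and KO ILC2 lists shared 93 WT peaks (6.90%) and 94 KO peaks (26.9%). Only 2 of the shared peaks overlapped no T cell region, on chromosome 3 at 56229688 to 56230072 (fold 7.11 in WT) and chromosome 2 at 170330497 to 170330716 (fold 4.58).

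**Figure D3:**
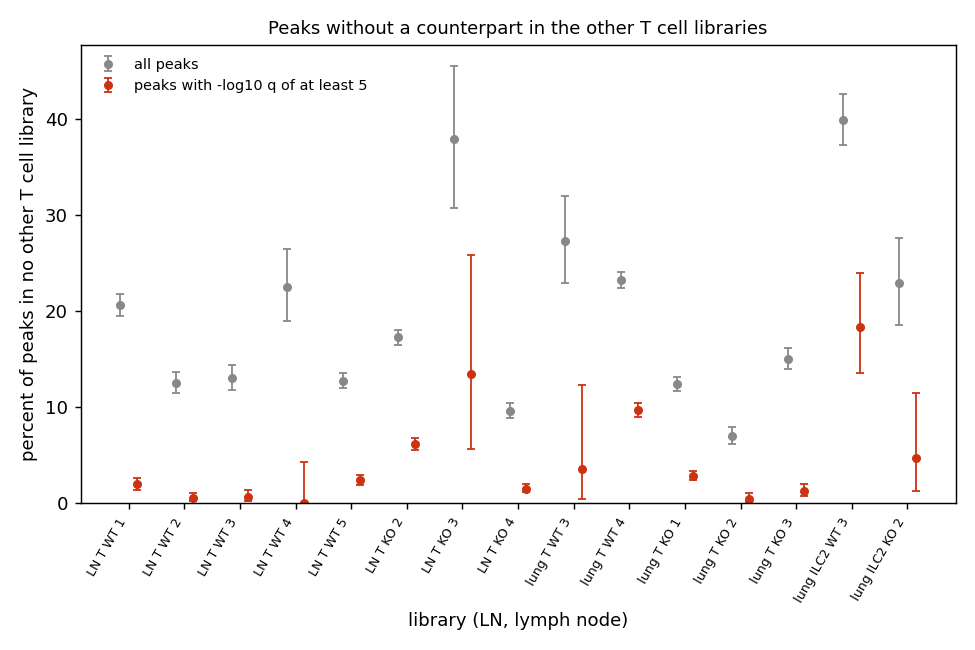
Percent of each library's peaks that overlap no region of the other T cell libraries, with exact 95% binomial intervals, for all peaks (grey) and for peaks with −log10 q of at least 5 (red). WT ILC2 stood at 39.9% and 18.3%, and the T cell libraries at 7.0% to 37.9% and 0 to 13.5%.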

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

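The test of background below was chosen after the results were seen. It replaced an earlier one that counted a region when any 1 library had a high background there, which favoured regions called in more libraries.

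Outside chromosomes 1 to 19, X and Y, the lists hold 849 peaks on unplaced contigs, and every library has some (11 to 105). The region and ILC2 comparisons left them out, while peak number and similarity counted them. They made up 1.36% of all peaks and between 0.916% and 7.41% of a library's. Among lymph node WT T cells, replicate 4 stood apart, with 4.42% of its 520 peaks on such contigs. Other short lists had such shares too: 5.85% in lymph node KO replicate 3, 4.12% in lung WT replicate 3 and 7.41% in KO ILC2. It was the only outlier among 8 measures examined in that group of 5, and chance marks about 1 measure in 20.

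The regions called in all 13 T cell libraries carry a high local background more often than less common regions do, within each library. A background over 10 times the library's lowest was found at 60% of a library's calls in these 35 regions (median over 13 libraries, 45.7% to 71.4%). It was found at 16.9% (8.73% to 28.8%) of its calls in regions called in 10 to 12 libraries and at 2.26% (1.19% to 5.88%) in those called in 2 to 9. In 13 of 13 libraries the share was higher in the first set than in the second, with separate exact intervals. A high background thus goes with common peaks, but its origin stays open. The sources used here do not say whether a control library was used, and without one a tall peak raises its own background. Repeated sequence and constitutive accessibility were not tested.

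WT ILC2 peaks without a T cell counterpart made up 39.9% of all peaks, 18.3% of those with −log10 q of at least 5 and 44.3% of the weaker ones. The T cell libraries ranged from 11.3% to 49.4% among weaker peaks, and the share was lower at the stricter threshold in every library. The 18.3% lay above the 0 to 13.5% of the T cell libraries at that threshold, although the highest of these came from lymph node KO replicate 3 with 52 such peaks (5.59 to 25.8). A difference between ILC2 and T cells stays open and was not tested. With 1 WT ILC2 library it cannot be separated from a property of that library.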

How the results depend on the processing

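The number of regions past adjustment stayed at 0 in each of the 24 alternatives of the tissue comparison, 17 of the lymph node and 13 of the lung genotype comparison. The design nearly fixes these 0 counts for genotype and in some tissue settings. For genotype the main setting needs 21 regions at the smallest possible p in lymph node, or 224 in lung. The 952 values of the 60 named regions under alternatives kept their direction and none passed adjustment, but the regions were chosen for their p, which leaves a turn little room. Of all 150 values that answer a comparison, 23 turned sign, each a difference in peak number or in similarity that was not past its threshold. The cause was not tested. The 150 include the counts of regions past adjustment, which stayed at 0 and have no sign to turn. Counts at an unadjusted p under 0.05 moved more, and what list lengths alone would give was not computed for every setting. In the tissue comparison (227 lung, 98 lymph node) they were 97 and 77 at the stricter threshold, 212 and 0 with Fisher's exact test, 202 and 53 with summit windows, 76 and 9 among WT, 54 and 13 among KO libraries, and 40 and 17 with the top 1000 peaks, which tests fewer regions. In lymph node (14 KO, 59 WT) they were 3 and 74 at the stricter threshold, 2 and 0 with Fisher's exact test, 0 and 50 without libraries of under 1000 peaks, and 0 and 10 with the top 1000 peaks. In lung (43 KO, 92 WT) they were 79 and 13 at the stricter threshold, 54 and 36 with summit windows, 44 and 45 without high-background peaks, and 43 and 0 without libraries of under 1000 peaks. Some of these 0 counts are fixed by the design: the smallest possible exact p was 0.330 towards KO in lymph node and 1 towards WT in lung without libraries of under 1000 peaks, and 0.1 in lung with Fisher's exact test. The excess of similarity within tissues (0.552 points) became −0.461 at the stricter threshold, −0.190 when ranking by fold and −0.565 without high-background peaks, but 1.64 without libraries of under 1000 peaks (exact permutation p = 0.12), 2.26 with the top 1000 peaks (exact permutation p = 0.06) and 2.44 with all peaks over the shorter list. The excess within genotypes in lymph node (2.34 points) became −2.47 without libraries of under 1000 peaks, −1.32 with all peaks over the shorter list and −2.26 with the top 1000 peaks. Peak number in lymph node, KO against WT (−0.36), became 0.16 at the stricter threshold and 0.80 without libraries of under 1000 peaks. That setting also turned the lung difference to −1.16, from 1 WT library, and the difference between the tissues' genotype effects to −1.96. The tissue difference in peak number was −0.41 among WT libraries. Leaving out each library in turn gave −0.81 to 1.54 for the tissue difference in peak number, −1.41 to 1.41 and −1.16 to 3.54 for the genotype difference in lymph node and lung, −0.80 to 3.89 for the difference between these, −0.766 to 1.98 points for similarity within tissues and −3.59 to 6.0 points for similarity within genotypes. Whether replicate numbers pair the samples cannot be settled from so few pairs. Deviations of same-numbered lymph node libraries correlated at −0.0348 to 0.253 over 3 pairs, and across tissues at −0.0394 to 0.197 over 4 pairs. Pairs of unlike number reached 0.0974 in lymph node and 0.191 across tissues. With the replicate block, peak number in lymph node was 0.36, similarity within tissues −1.12 points, and 0 regions passed adjustment, with 74 and 40 (tissue) and 21 and 26 (lymph node genotype) at an unadjusted p under 0.05. Leaving out high-background peaks and the top 1000 peaks were settings chosen after seeing the data. Promoter shares, genes called and gene lists were not run for want of an mm9 annotation here. Median summits were 6 to 13 reads and 3 T cell libraries had under 1000 peaks. Read numbers are not given in the sources used here, so depth was not separated from enrichment quality.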

Other observations

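The tests below were chosen after the region calls were seen, and the peak shares per chromosome were added as a description. T cells of lung placed a smaller share of their peaks on chromosome 18 than lymph node T cells, 2.69% ± 0.0632 (SD, n = 5) against 3.27% ± 0.694 (SD, n = 8), with a stratified difference of −0.632 points (exact permutation p = 0.00476, adjusted over 20 chromosomes 0.0952). They placed a larger share on chromosome 9, 5.21% ± 0.256 against 4.44% ± 0.843 (difference 0.835 points, exact permutation p = 0.00952, adjusted p = 0.0952), and on chromosome 11, 6.67% ± 0.547 against 5.30% ± 1.43 (difference 1.42 points, exact permutation p = 0.0429, adjusted p = 0.286). None passed adjustment, and no chromosome did so for genotype.

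Call profiles of the T cell libraries went with tissue. After removing what list length and the commonness of a region predict, the calls of 2 libraries of one tissue correlated at −0.0517 on average over 10254 regions and those of libraries from different tissues at −0.0991. The difference of 0.0473 was the highest of 420 arrangements of tissue within genotype (1-sided exact permutation p = 0.00238, the smallest these can give), and it stayed between 0.0328 and 0.0547 when each library was left out in turn. Grouping by genotype within tissue gave −0.00463 (1-sided exact permutation p = 0.654), which lies within the spread of the arrangements and decides nothing. The rule for that test was changed after its value was seen. The tissue difference per region in WT libraries correlated with that in KO libraries, which are separate samples, at r = 0.118 over 9142 regions (1-sided exact permutation p = 0.00476 over 420 arrangements). Regions are not independent replicates, and the p comes from rearranging libraries.

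The number of regions that differ between the tissues at an unadjusted p was seldom reached by other splits of the 13 libraries. The real split gave 325 regions, reached by 2 of 100 splits with the real one included, the highest other split giving 331. The splits were drawn without regard to genotype and the rule was set after the calls were seen. Chance is thus made less likely but is not excluded. That holds for this count alone and depends on single libraries. The count was 134 without lung KO replicate 1 and 198 without lymph node KO replicate 2. List lengths alone would give 78.2 and 128, and no splits of these smaller sets were run. After adjustment 1 other split had a region and the real one 0. For KO against WT in lymph node chance stays open, since 33 of 56 splits gave as many as the real 73 regions and the highest other gave 217. Unequal list lengths are not ruled out as a source of the tissue difference: with the 1000 strongest peaks of each of 10 libraries the excess similarity within tissues was 0.0489, in the same direction (1-sided exact permutation p = 0.08 over 50 arrangements). With all peaks of these 10 libraries, whose lists stay unequal, it was 0.0646 (1-sided exact permutation p = 0.02, the smallest possible). If library numbers follow processing order, which the labels do not say, it cannot be told apart from tissue, since lymph node libraries carry the lower numbers. Within the 8 lymph node libraries similarity fell little with the difference in library number (r = −0.143, 2-sided exact permutation p = 0.507). Tissue itself, and culture of lymph node cells if it applied to these libraries, may account for the difference and were not tested apart.

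A hypothesis that lung ILC2 share the regions preferred by lung T cells found no clear answer. The WT ILC2 library called 11 of the 227 such regions, against 8.69 on average in 1000 draws of regions called by as many T cell libraries (4 to 14 in 95% of draws). Of the 98 regions preferred by lymph node T cells it called 3, with 4.72 on average in the draws.

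Lung-preferring regions were also examined for shared neighbourhoods, as parts of one locus might open together. Among the 227 regions, 9 neighbouring pairs lay within 100 kb, against 5.30 in 1000 matched draws (1 to 10 in 95% of draws), which does not settle the question. The closest pair lay 6981 bp apart on chromosome 8, at 129356220 to 129356784 and 129363265 to 129363700, each called in 3 of 5 lung and 0 of 8 lymph node libraries. On chromosome 1, regions at 61102871 to 61103546 and 61111276 to 61111911, 8385 bp apart, were called in 4 and 3 of 5 lung libraries and in 0 of 8 lymph node libraries. These pairs were named after their values were seen. The 98 lymph node regions held 0 such pairs, with 0.944 on average in the draws.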
